A study of Daphnia magna with 80 samples.

How the data were processed

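Whole Daphnia magna of strain Bham2 were frozen at known ages, when the brood pouch of females was empty, and RNA was taken from samples of about equal dry mass, per the labels' protocols. Libraries were made with the Illumina TruSeq mRNA kit and read as pairs of 100 bases on an Illumina HiSeq instrument, per the labels' protocols. TopHat2 2.1.1 and DESeq2 1.20 are listed in the submitters' processing notes. The counting tool, its strand setting, the genome build and the annotation are not given in the sources used here, so the counts of near-identical or overlapping genes are uncertain.

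The deposited count table holds whole-number counts, not normalised, for 26646 gene IDs and 7 rows of synthetic spike-in RNA (SIRV) in 80 columns. The spike-in rows name no gene and were kept out of library sizes and tests, except in an alternative with library sizes set by them. They held 0.22% to 2.31% of the counts of a column. The authors deposited 3 further tables, of an age effect, a sex effect and their interaction, with age in days. Per the file headers each gives a mean of counts divided by size factors (a normalised signal), a log2 change with its standard error, a score (the change divided by its standard error), a p-value and an adjusted p-value. The model and the libraries behind them are not given in the sources used here. The deposited mean counts equalled those computed here (largest relative difference 0%, to 3 decimals, for genes with a mean over 10) when the 76 libraries with a group were used with the technical runs summed, and differed by a median of 1.03% with the runs kept apart.

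Sex, age and replicate number came from the sample titles. Of the 80 columns, 3 belong to samples that the labels mark as mislabelled and excluded, and these entered no comparison. A further 2 columns are technical replicates of 1 male 10-day sample and were summed, which left 76 biological samples. No 2 libraries had identical counts, and the highest correlation of log2 CPM between 2 libraries was 0.982. The 3 shallowest libraries held at most 5058275 gene counts, and each other library at least 8901627.

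Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM library sizes, filterByExpr, quasi-likelihood F-test, Benjamini-Hochberg adjustment, adjusted p under 0.05). Models held sex and age for the sex and common age effects, sex, age and their product for the interaction, and age alone within each sex. Slopes are log2 changes per 10 days, and the standard error is the size of the change divided by the square root of F. CPM are counts divided by the TMM-scaled library size, in the usual unit, and log2 CPM used a prior count of 2. Because the files give IDs without names and 0 IDs matched the reference table, the gene lists chosen beforehand could not be tested, and at most 2 IDs that rose and 2 that fell were named per comparison, those with the smallest p and a mean log2 CPM of at least 3. Tests, groups, this rule and most alternatives were fixed before the data were examined.

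The alternatives were relative log expression scaling, no filter on low counts, DESeq2 1.42.0, limma-voom (limma 3.58.1) with quality weights, a replicate block, log2 library size as a covariate, either technical run alone, other codings and ranges of age, and leaving out each library in turn. Added after the data were seen were spike-in library sizes, fits without the block of 7 abundant genes, without the 3 shallowest libraries, with females of 45 to 80 days alone, with both sexes at 10 to 40 days, with the spike-in cluster as a covariate and within each cluster. The clusters rest on 2 of the 7 spike-ins: they divide the libraries by the log2 ratio of SIRV7 to SIRV1 (medians -0.32 and 0.10, range -0.976 to 0.244) at the widest gap, 0.095, once the lowest and highest 10% of libraries were left aside. At the low end 2 wider gaps (up to 0.226), with 3 libraries below them, were not used. The sex score is the mean log2 CPM of male-biased less that of female-biased genes, so that a common shift of library size does not move it. Correlations across samples were tested 2-sided with 100000 permutations (all permutations with fewer than 10 values), of which 1e-05 is the smallest p. Figures were drawn with matplotlib 3.10.9.

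The fits were tested on simulated counts with 200 changed genes, using the means and library sizes of the real data and the fitted trend of the dispersion. For sex, with 17233 genes tested, 85 of 100 genes changed by 1 and 100 of 100 changed by 2 on the log2 scale were recovered. Of 100 slopes of 0.25 per 10 days, 91 were recovered for age in both sexes (17222 genes), 69 in females (16114 genes) and 13 in males (16382 genes). For the interaction (17389 genes), 68 of 100 differences of 0.5 and 5 of 100 differences of 0.25 were recovered. False calls numbered 4 of 189 for sex and 4 of 77 for the interaction. Far more genes were called in the real data, where the adjusted threshold is therefore less strict. These rates do not carry over to the real data.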

Results

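The study measured whole-animal gene expression in the water flea Daphnia magna, a planktonic crustacean whose females can produce genetically identical daughters and sons. Females and males of 1 strain, Bham2, were sampled across adult life to ask how expression differs between the sexes and with age when the genotype is shared. Females came from 15 ages between 10 and 80 days (39 libraries), and males from 13 ages between 8 and 40 days (37 libraries). Most sex-and-age groups held 3 libraries. Among the female groups 10 held 3, 4 held 2 and 1 held 1, and among the male groups 11 held 3 and 2 held 2. Gene counts per library ranged from 2242215 to 27789716 in females (median 19077345) and from 1599627 to 33480868 in males (median 19608955). The labels do not say whether replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be partly technical. Gene IDs are given as in the files, which do not pair them with names, and none of the 26646 IDs matched the reference table used here.

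Sex was the main axis of the data. The first principal component of the 2000 most variable genes held 56.5% of their variance and parted the sexes without overlap, from -107.9 to -18.96 in females and from 29.36 to 97.52 in males. At a given age, 5935 genes were higher and 5948 lower in males, together 68.1% of the 17443 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Large differences were found in both directions. Among the called genes, 1018 were at least 4-fold higher in males and 594 at least 4-fold higher in females, and differences of at least 64-fold were found for 65 and 102 genes. APZ42_018003 stood at 195.6 CPM ± 58.6 (SD, n = 37) in males and 6.24 CPM ± 2.73 (SD, n = 39) in females, a log2 change of 5.08 ± 0.17 (SE, adjusted p = 6.04e-42). APZ42_021578 was also higher in males, by 3.18 ± 0.098 (SE, adjusted p = 2.28e-43) on the log2 scale. APZ42_033120 stood at 207.4 CPM ± 144 (SD, n = 39) in females and 0.978 CPM ± 0.569 (SD, n = 37) in males, a log2 change of -8.00 ± 0.22 (SE, adjusted p = 1.21e-45). For APZ42_024848, the levels were 179.7 CPM ± 105 (SD, n = 39) in females and 4.01 CPM ± 1.55 (SD, n = 37) in males, a log2 change of -5.81 ± 0.16 (SE, adjusted p = 1.21e-45). Expression limited to 1 sex was looked for with 2 measures, the first of which fails with 1 stray count in any library and so does not show how rare it was. No gene with a median of at least 5 CPM in 1 sex was without a count in every library of the other, while 39 such genes in females and 27 in males had a median under 0.1 CPM in the other sex.

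The sex difference was also estimated in separate sets of libraries. The ratio of 2 of the 7 synthetic spike-in RNAs was used to divide the libraries into 2 clusters of 48 and 28, which held 24 and 15 female libraries. Fitted within each cluster, the log2 changes by sex correlated across 17112 genes (Pearson r = 0.941, Spearman rho = 0.895; genes are not independent replicates), and 7946 of the 7953 genes called in both had the same direction. With library sizes set by the spike-ins, 37.6% of the called genes were higher in males in place of 49.9%, and the sex change of the median gene moved by -0.20 on the log2 scale.

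In females, 3549 genes rose and 3283 fell with age between 10 and 80 days, together 41.9% of 16300 genes tested (edgeR, adjusted p under 0.05). The median absolute slope among called genes was 0.151 on the log2 scale per 10 days. APZ42_015229 rose from 15.3 CPM ± 1.08 (SD, n = 3) at 10 days to 71.1 CPM ± 5.74 (SD, n = 3) at 80 days, a slope of 0.35 ± 0.028 (SE, adjusted p = 1.06e-11). APZ42_030362 rose from 3.75 CPM ± 0.79 to 13.2 CPM ± 1.31 (SD, n = 3 each) at the same ages. APZ42_031663 fell from 1473 CPM ± 257 (SD, n = 3) to 368.8 CPM ± 78.8 (SD, n = 3), a slope of -0.40 ± 0.038 (SE, adjusted p = 7.77e-10). APZ42_016793 fell from 166.2 CPM ± 20.0 to 52.2 CPM ± 8.51 (SD, n = 3 each). These directions are relative to the median gene. With spike-in library sizes the median slope moved by -0.15 per 10 days, and 4.3% of the called genes rose in place of 51.9% (400 rose and 8852 fell). Within the spike-in clusters, 5367 genes were called in the larger and 74 in the smaller (15 female libraries with a median age of 35 days, against 24 with a median of 45 days), and the slopes correlated across genes (Pearson r = 0.75, Spearman rho = 0.778).

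Fewer genes were called within early or late female ages alone. With ages of 10 to 40 days alone, 691 genes rose and 443 fell, and with ages of 45 to 80 days alone 1 gene was called by edgeR over 20 libraries, with 1308 of 16194 genes at an unadjusted p under 0.05 where 810 are expected by chance, and 124 called by DESeq2. Slopes from those separate libraries were weakly correlated across 15669 genes (Pearson r = 0.147, Spearman rho = 0.116), and 55.2% of the genes called at 10 to 40 days kept their sign at 45 to 80 days. These sets hold fewer libraries over shorter ranges, and how many calls a steady slope would give there was not tested.

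In males, 2522 genes rose and 2905 fell with age between 8 and 40 days, 32.7% of 16606 genes tested (edgeR, adjusted p under 0.05). The named genes changed several-fold within these weeks. APZ42_002290 rose from 46.7 CPM ± 3.75 (SD, n = 3) at 8 days to 240.7 CPM ± 26.2 (SD, n = 3) at 40 days, a slope of 0.94 ± 0.067 (SE, adjusted p = 4.83e-13) on the log2 scale per 10 days. APZ42_020248 rose from 89.4 CPM ± 5.21 to 387.7 CPM ± 48.8 (SD, n = 3 each). APZ42_031663, which also fell in females, fell from 1080 CPM ± 128 (SD, n = 3) to 147 CPM ± 10.6 (SD, n = 3), a slope of -0.89 ± 0.069 (SE, adjusted p = 3.75e-12). APZ42_021034 fell from 717.2 CPM ± 43.3 to 182.5 CPM ± 17.6 (SD, n = 3 each). Spike-in library sizes lowered the calls to 995 and 1237. Within the spike-in clusters, 3117 and 3282 genes were called, and 1116 of the 1123 called in both had the same direction. Over all genes the slopes of the clusters correlated moderately (Pearson r = 0.418, Spearman rho = 0.457), and 83.6% of the calls in the larger had the same sign in the smaller.

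Age changed many of the same genes in the same direction in both sexes. Of the 15734 genes tested in both, 3057 were called in each sex, and 2846 of these (93.1%) changed in the same direction. In all 1430 genes rose in both sexes against 545 expected of independent lists, and 1416 fell in both against 560 expected. Opposite directions were rarer than expected: 117 genes rose in females and fell in males (613 expected), and 94 did the reverse (498 expected). Over all genes tested in both, female and male slopes correlated (Pearson r = 0.515, Spearman rho = 0.524; across genes, which are not independent replicates). The female and male libraries are separate, so no shared control enters this comparison. With females of 10 to 40 days alone the correlation was 0.325. In a model of both sexes with 1 common slope, 3965 genes rose and 4549 fell (edgeR, adjusted p under 0.05; 17443 genes). With spike-in library sizes 793 rose and 8864 fell. In the smaller spike-in cluster 1128 genes were called and in the larger 7573, and 971 of the 972 called in both had the same direction.

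**Figure D1:**
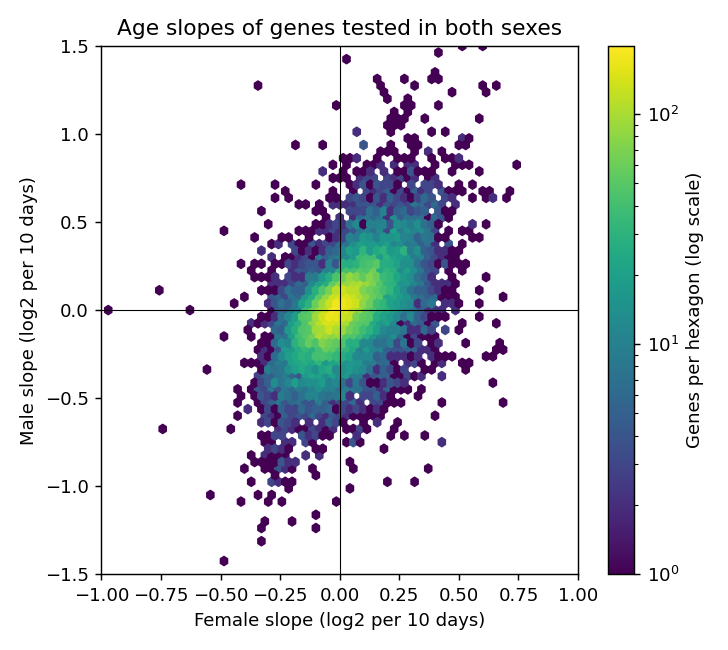
Age slopes of the 15734 genes tested in both sexes, female on the horizontal and male on the vertical axis (both log2 per 10 days), with colour for the number of genes per hexagon on a log scale. The slopes correlate across genes with wide scatter (Pearson r = 0.515), and 7 genes lie outside the plotted range.

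Slopes differed between the sexes for 2136 of 17706 genes (12.1%, edgeR interaction test, adjusted p under 0.05). The named genes changed in males and little or less in females. APZ42_016642 rose in males from 1.51 CPM ± 0.211 (SD, n = 3) at 8 days to 10.8 CPM ± 1.62 (SD, n = 3) at 40 days, while females stood at 11.1 CPM ± 0.502 at 10 days and 11.9 CPM ± 0.62 (SD, n = 2) at 40 days. The difference of slopes was 0.83 ± 0.073 (SE, adjusted p = 8.55e-14) on the log2 scale per 10 days. APZ42_013478 differed by 0.84 ± 0.092 (SE, adjusted p = 2.46e-10), from 1.93 CPM ± 0.404 (SD, n = 3) in males of 8 days to 14.3 CPM ± 2.66 (SD, n = 3) at 40 days. APZ42_025850 fell in males from 1090 CPM ± 16.3 (SD, n = 3) to 339.2 CPM ± 24 (SD, n = 3), and its slope was lower in males by -0.55 ± 0.054 (SE, adjusted p = 6.03e-12). For APZ42_021034 the difference was -0.43 ± 0.045 (SE, adjusted p = 4.94e-11), with slopes of -0.57 in males and -0.15 in females. Both slopes could be tested for 2034 of the called genes. The male slope alone was called for 981 of them and the female slope alone for 292. Both were called with the same sign for 531 and with opposite signs for 208, and neither for 22. The male slope was above the female slope for 803 of the 2136 genes and below it for 1333, a balance that differed between settings: 1212 and 1055 without the 7 abundant genes described below, where the difference of slopes of the median gene moved by 0.027 per 10 days, and 984 and 139 with spike-in library sizes, where it moved by 0.131. Within the spike-in clusters 632 and 1902 genes were called, and 192 of the 193 called in both had the same direction, while over all genes the differences of slopes correlated weakly between the clusters (Pearson r = 0.298, Spearman rho = 0.34).

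**Figure D2:**
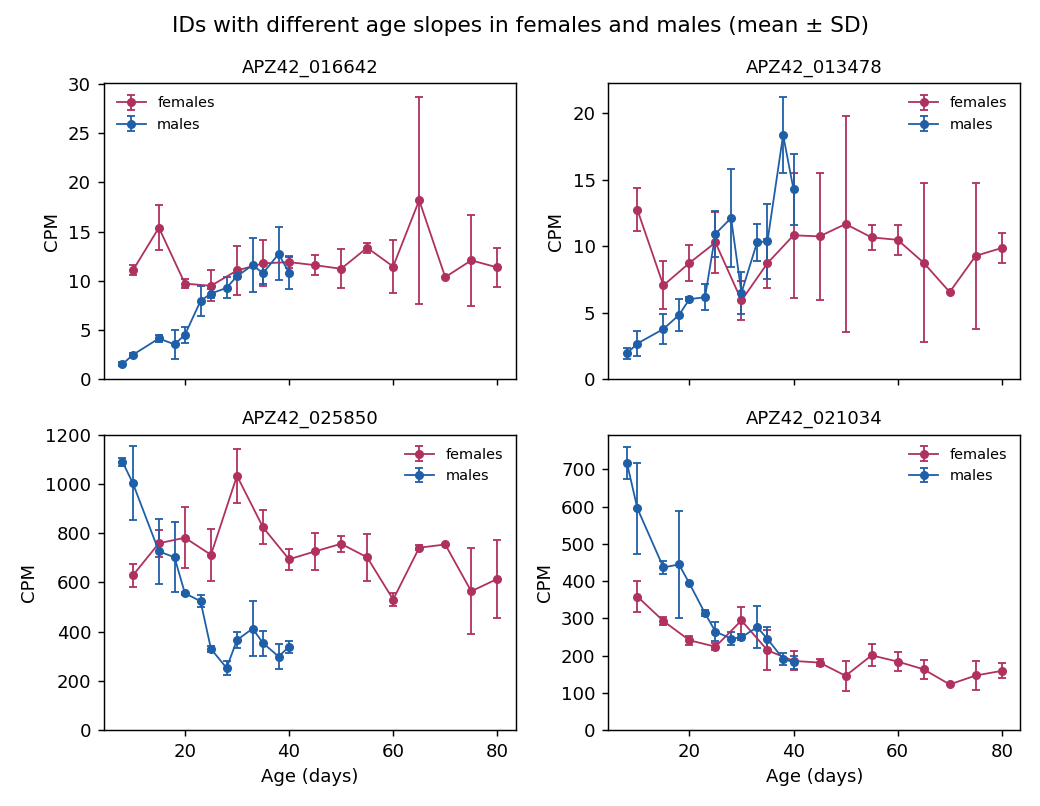
CPM of the 4 named genes whose age slopes differed between the sexes, by age in days. Points are group means and bars are 1 SD (n = 1 to 3 per group, no bar at n = 1). In males APZ42_016642 and APZ42_013478 rose and APZ42_025850 and APZ42_021034 fell over 8 to 40 days.

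Sex-biased genes as a group moved with age in females. From the 26 replicate 1 libraries, 2481 male-biased and 1768 female-biased genes were chosen (adjusted p under 0.05, at least 2-fold), and a score of 0 at the female and 100 at the male mean of those libraries was computed in the other libraries. Females of 10 to 25 days scored -17.8 ± 9.7 (SD, n = 7), females of 30 to 45 days -12.8 ± 13.8 (SD, n = 7) and females of 50 to 80 days 22.8 ± 9.0 (SD, n = 12). Of the libraries used to choose the genes, which are not plotted, the 30-day female scored 20.6, inside the range of the plotted females of 50 to 80 days, and the 55-day female 4.9, below it. The score rose with age over the 26 female libraries (Pearson r = 0.769, permutation p = 2e-05, adjusted 0.00012; Spearman rho = 0.751, permutation p = 3e-05, adjusted 0.00012; r = 0.802 without the 2 libraries farthest from the median age). Over 24 male libraries it rose too (Pearson r = 0.561, permutation p = 0.00488, adjusted 0.00732; Spearman rho = 0.551, permutation p = 0.00597, adjusted 0.00716; r = 0.433 without the 2 farthest). Female-biased genes fell by a mean of -0.19 ± 0.032 (SE, n = 26) in females and -0.18 ± 0.048 (SE, n = 24) in males on the log2 scale per 10 days, and male-biased genes rose in females by 0.098 ± 0.032 (SE, n = 26), less than the shift of -0.15 of the median female slope with spike-in library sizes, so that this rise holds only relative to the median gene. In males the slope of male-biased genes was 0.040 ± 0.037 (SE, n = 24, permutation p = 0.29). These were 6 relations, adjusted together. All permutations of the score treated libraries of 1 age group as independent. Departures shared by a group would make these p-values too small. Within the spike-in clusters the female correlation was 0.81 (permutation p = 0.00011, n = 17) and 0.659 (exact permutation p = 0.0529, n = 9).

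**Figure D3:**
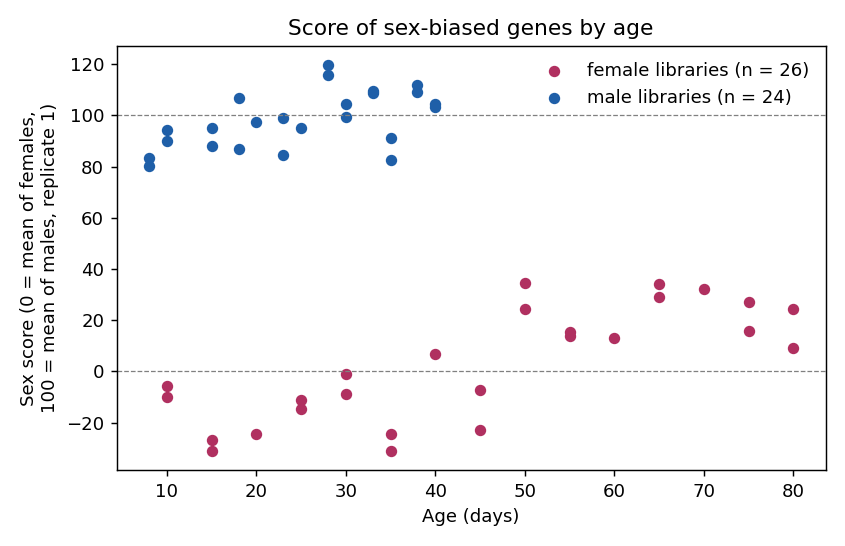
Score of sex-biased genes (0 and 100 are the means of female and male replicate 1 libraries) against age in days, 1 point per library not used to choose the genes. Female libraries of 50 to 80 days lie between 9.0 and 34.7, above the plotted female libraries of 10 to 45 days, whose highest is 6.6.

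The share of counts taken by the synthetic spike-ins rose with age in females of 10 to 40 days. Relative to gene counts outside the abundant genes described below, the share was 0.815% ± 0.234 (SD, n = 19) in females of 10 to 40 days, 1.33% ± 0.497 (SD, n = 20) in females of 45 to 80 days and 1.12% ± 0.313 (SD, n = 34) in males of 10 to 40 days. Its log2 rose with age over the 39 female libraries (Pearson r = 0.657, permutation p = 2e-05, adjusted 4e-05; Spearman rho = 0.63, permutation p = 4e-05, adjusted 8e-05; r = 0.603 without the 2 libraries farthest from the median age) and over the 19 of 10 to 40 days (Pearson r = 0.844, Spearman rho = 0.853, both with a permutation p of 1e-05, the smallest they can give, adjusted 4e-05; r = 0.803 without the 2 farthest). No relation was detected over the 20 of 45 to 80 days (Pearson r = -0.037, permutation p = 0.88, adjusted 0.918; Spearman rho = -0.191, permutation p = 0.418, adjusted 0.557; r = 0.091 without the 2 farthest), a relation tested after the values were seen. No relation was detected in 37 male libraries (Pearson r = -0.018, permutation p = 0.918; Spearman rho = -0.027, permutation p = 0.873; r = -0.162 without the 2 farthest). These 4 relations were adjusted together. All permutations of the spike-in share treated libraries of 1 age group as independent, so departures shared by a group would make these p-values too small. Within the spike-in clusters the female correlations were 0.666 (permutation p = 0.00034, n = 24) and 0.654 (permutation p = 0.00819, n = 15). At the 7 ages sampled in both sexes the share was higher in males by 0.50 on the log2 scale (permutation p = 0.00084, 2-sided, 19 libraries of each sex), and over all ages it differed by 0.061 (permutation p = 0.608, 39 female and 37 male libraries). How the spike-ins were dosed is not given in the sources used here, so the share is not converted to an amount of RNA.

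**Figure D4:**
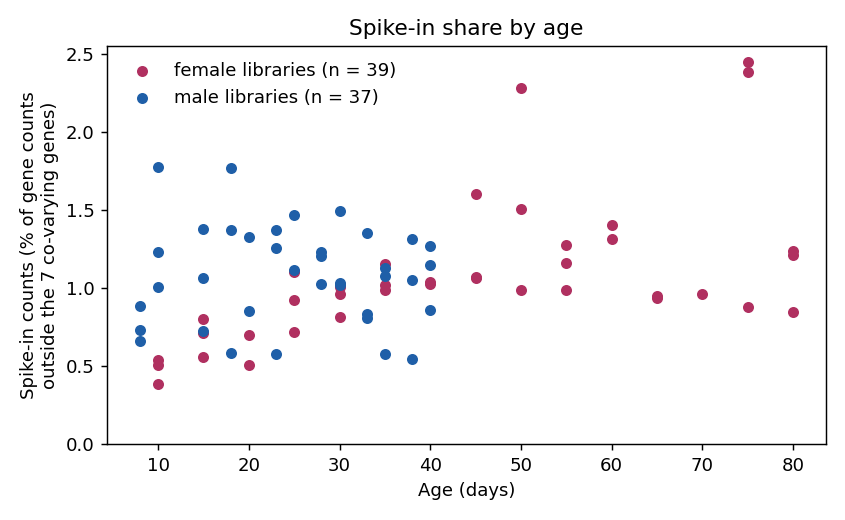
Spike-in counts as a percent of gene counts outside the 7 co-varying genes, by age in days, 1 point per library. The share lies between 0.386% and 1.16% in females of 10 to 40 days and between 0.846% and 2.45% in females of 45 to 80 days.

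A block of 7 abundant genes varied together between libraries. Their log2 CPM correlated at 0.9 or more with that of APZ42_024615, the most abundant gene, singled out after its values were seen, which took a mean of 8.03% of gene counts. The block held from 1.03% to 75.4% of the gene counts of a library (median 17%), and more than 30% in 14 libraries. None of the 7 genes was called for sex by edgeR (0 at an unadjusted p under 0.05), 1 was by DESeq2 and 0 by limma. The medians were 15.1% in females and 20.9% in males (permutation p = 0.266 on the log2 scale). In 1 male sample of 10 days that was run as 2 technical replicates, the block held 0.696% of 13272221 counts in 1 run and 40.6% of 20208647 in the other.

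**Figure D5:**
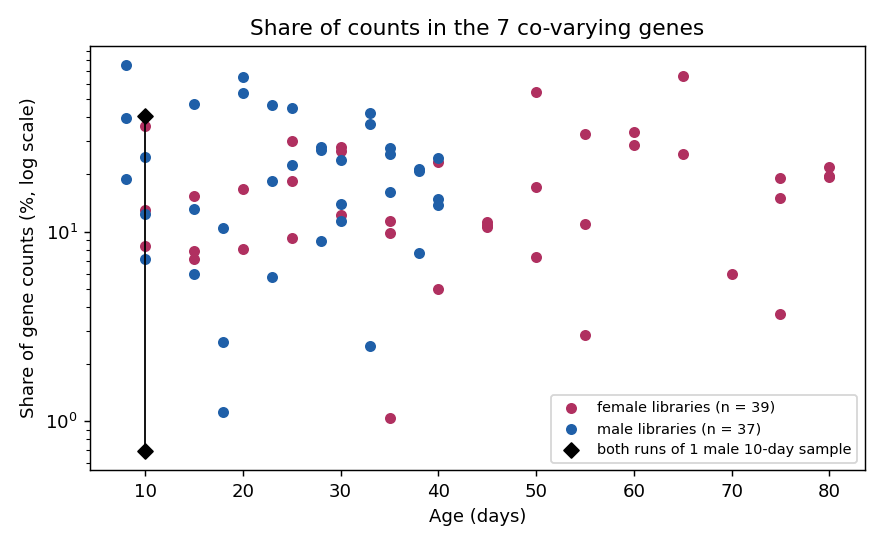
Share of gene counts in the 7 co-varying genes (percent, log scale) by age in days, 1 point per library, with both technical runs of 1 male 10-day sample as joined diamonds. The runs lie at 0.696% and 40.6%, while the 76 libraries span 1.03% to 75.4%.

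The authors' deposited tables of sex, age and interaction effects were compared with fits of the counts. In the authors' deposited table of the interaction 1063 genes were positive and 1678 negative at an adjusted p under 0.05, and its values correlated with the interaction changes here across genes (Pearson r = 0.99). The authors' deposited table of the age effect held 4934 positive and 3705 negative genes. Its values differed by a median of 0 from the female slope of a DESeq2 model with an interaction, and by 0.0019 per day from the slope of a model with 1 common slope, over 15723 genes. The authors' deposited table of the sex effect (3595 positive and 5002 negative) matched, with its sign changed, the male effect of the same interaction model, which is the difference extrapolated to an age of 0 days. That authors' deposited table codes female over male, and of the genes called both there and here 7136 had opposite signs and 54 the same.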

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

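The tests with ages of 10 to 40 days in both sexes, spike-in library sizes, the spike-in cluster, without the abundant genes and with the sex score were chosen after the data were seen.

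The effect of age differed between the sexes for 2136 genes by the interaction test, with a difference of slopes (male minus female, log2 per 10 days) of 0.83 for APZ42_016642, 0.84 for APZ42_013478, -0.55 for APZ42_025850 and -0.43 for APZ42_021034. The abundant genes as the whole cause were argued against by a count of 2267 without them. A count of 2367 with library size as a covariate argued against depth, as an effect common to both sexes. With the spike-in cluster as a covariate the count was 2427, but the cluster is not settled by this. Fits within the clusters gave 632 and 1902 calls, over fewer libraries, and their differences of slopes correlated weakly (Pearson r = 0.298). Other settings lowered the count too, to 1123 with spike-in library sizes and 1419 at ages up to 40 days. The unequal age ranges stay open. With ages of 10 to 40 days in both sexes (19 female and 34 male libraries) 1208 genes were called. However, 2 of 40 assignments of the ages, the real one included, gave as many (highest other 1367, median 0), so these ages alone do not decide. The shuffles also removed the age effect of each sex, so they do not test equal slopes. Of 2132 calls tested again at ages up to 40 days, 817 were called again and 98.1% kept their sign, which decides nothing as the libraries overlap, and with age as a share of the oldest age 1286 of the 2136 were called again and 995 others were called. A biological difference between the sexes stays open too, as a hypothesis.

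The male slope was above the female slope for 803 of the 2136 genes and below it for 1333, and this balance was not stable. The counts were 1212 above and 1055 below without the abundant genes and 984 and 139 with spike-in library sizes. The count above was 1226 without female 60-day replicate 3, 1294 without female 30-day replicate 3, 1309 without female 75-day replicate 2 and 1231 without male 30-day replicate 1.

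Over all ages, shuffled labels gave fewer genes than the real labels in each comparison. Of 40 assignments of the labels, the real one included, only the real one (1 of 40) gave as many genes in each of the 5 comparisons. Shuffled sex gave at most 353 genes against 11883. Ages shuffled within each sex gave at most 1383 against 8514 for age in both sexes, 11 against 2136 for the interaction, 123 against 6832 for females and 39 against 5427 for males. These shuffles remove the age effect of both sexes and break up the age groups. For the interaction they stand for no age effect, not for equal slopes, so they do not decide whether the slopes differ.

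The 3 samples that the labels mark as mislabelled were outside all comparisons, and their sex scores were 93.7, -12.0 and -17.8 on the scale where replicate 1 females average 0 and males 100. The first carries a female title and the others male titles. On the first principal component they lay at 62.64, -84.67 and -99.82.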

How the results depend on the processing

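Spike-in library sizes, the fits without the abundant genes or the shallowest libraries, those with spike-in clusters, females of 45 to 80 days alone and both sexes at 10 to 40 days were chosen after the data were seen. The 16 named results kept their sign in all 252 values under the alternatives and all 912 values with 1 library left out, and fell below the threshold in 8 of the former and 0 of the latter. They were picked for the smallest p in these same libraries, so this does not speak for the other called genes. Of the planned values of counts and of the slope correlation, 142 stayed near the reported value (counts within 1.5 times) and 11 did not, and of those added later 68 did and 35 did not. Where no construction is named, the cause was not tested.

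Replicate numbers did not pair the libraries: residuals of the same number correlated by -0.0014 on average and those of different numbers by 0.001, and 29 of 75 libraries lay nearest to their own number. With the replicate block 11979 genes were called for sex, 8353 for age in both sexes, 2225 for the interaction (1203 and 1022), 6672 in females and 5438 in males, and no count moved by over 1.5 times.

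Ages up to 40 days, with fewer libraries, gave 2046 risen genes for age in both sexes, 1419 interaction calls (867 with a lower male slope), 1134 calls in females (691 and 443) and a slope correlation of 0.325. Both sexes at 10 to 40 days gave 1208 interaction calls (714 above and 494 below). Females of 45 to 80 days (20 libraries) gave 1 call by edgeR (1 risen, 0 fallen, 1308 genes at an unadjusted p under 0.05), 124 by DESeq2 and a slope correlation of 0.26. The gene list tests were not run, as the IDs carry no names. Limma-voom gave 4163 interaction calls (1725 and 2438), and no filter on low counts a slope correlation of 0.301. Spike-in library sizes gave 3825 genes higher in males, 793 risen and 8864 fallen with age in both sexes, 1123 interaction calls (139 with a lower male slope), 400 risen and 8852 fallen in females and 2232 calls in males (995 and 1237). The count of interaction genes with the male slope above the female slope was 1212 without the abundant genes, 1436 without the shallowest libraries and 1358 with the spike-in cluster as a covariate. The larger cluster gave 632 interaction calls (316 and 316) and 3117 in males (1576 and 1541). The smaller, with 28 libraries, gave 1128 for age in both sexes (737 and 391), 74 in females (67 and 7), 3282 in males (1525 and 1757) and a slope correlation of 0.263.

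With 1 library left out, counts ranged from 11675 to 12025 for sex, 8042 to 8662 for age in both sexes, 1770 to 2574 for the interaction, 6118 to 7077 in females and 4833 to 5887 in males. Interaction genes with a higher male slope ranged from 696 to 1309, and numbered 1226 without female 60-day replicate 3, 1294 without female 30-day replicate 3, 1309 without female 75-day replicate 2 and 1231 without male 30-day replicate 1. Those with a lower male slope ranged from 908 to 1435. On simulated counts, 69 of 100 slopes of 0.25 were recovered in females, sampled over 10 to 80 days, and 13 in males, sampled over 8 to 40 days. These rates do not carry over to the real data, where far more genes were called and the adjusted threshold was less strict. Without the 3 shallowest libraries 2708 interaction genes were called.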

Other observations

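The tests of the sex score, of both technical runs, of the spike-in clusters, of the pace of change and of a step in female age were chosen after the results were seen.

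Part of the female age change may lie in a step in midlife. Over 16298 genes, a single step between 45 and 50 days explained 15.9% of the variance of log2 CPM in the 39 female libraries, and a straight line in age explained 14.24%. The 12 steps tried ran from that between 15 and 20 days to that between 70 and 75 days, without the outermost ones. Of these the step between 45 and 50 days explained most. Its excess of 1.66 points over the line exceeded nearly all of 2000 datasets made from the line with its residuals shuffled between libraries (permutation p = 0.0055, n = 39, median excess -2.12 points). It stayed at the same ages without the shallowest libraries (permutation p = 0.006, n = 37) and in the larger spike-in cluster (permutation p = 0.0385, n = 24), where step and line explained nearly the same (18.44% and 18.18%, an excess of 0.26 points). In males the best of the 10 steps tried, between 25 and 28 days, explained less than the line (9.92% against 12.28%, permutation p = 0.517, n = 37). A step in the female profile between 45 and 50 days is a hypothesis, since the position was found and tested on the same libraries. The shuffles also treated libraries of 1 age group as independent. A departure from the line shared by a group would make these p-values too small. No curve other than the line was set against the step.

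Replicates of older females also lay farther apart. The mean absolute log2 difference between replicates rose over the 14 female age groups (Spearman rho = 0.745, permutation p = 0.00328, adjusted 0.00656; Pearson r = 0.676, permutation p = 0.00712, adjusted 0.0142; r = 0.843 without the 2 groups farthest from the median age). It was 0.452 at 10 days and 1.199 at 75 days, and 0.566 at 80 days. Without the shallowest libraries the relation was smaller but still found (Spearman rho = 0.676, permutation p = 0.0136; Pearson r = 0.587, permutation p = 0.0351; 13 groups). No relation was detected over 13 male age groups (Spearman rho = -0.374, permutation p = 0.209; Pearson r = -0.221, permutation p = 0.468). The difference between the sexes was not tested.

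The sex score placed old females nearer to the fixed male mean than young females. The score also rose with age in males, by 5.94 ± 1.9 (SE, n = 24) per 10 days, against 7.56 ± 1.3 (SE, n = 26) in females. Male RNA in the libraries of old females would need a share of 57.2% to give the median fall of 1746 female-biased genes. In females of 45 to 80 days 61 genes nearly limited to males put the share at 0.877%, which argues against male RNA as the source. The share of 0.158% at 10 to 40 days was held low by the choice of genes, which used females of these ages. The rise of the score with age kept a permutation p of 2e-04 with library size as a covariate (7.28 per 10 days) and of 1e-04, the smallest 10000 permutations can give, with the spike-in cluster as a covariate (7.52 per 10 days). A fall in egg production with age, which would lower female-biased transcripts, may be behind the pattern and stays open, since no measure of reproduction was used here. Female-biased genes fell with age in males too (Spearman rho = -0.612, permutation p = 0.00191, adjusted 0.00382; Pearson r = -0.632, permutation p = 0.00109, adjusted 0.00218; 24 libraries). Egg production alone would not give this fall in males. The permutations behind these p-values of the score and its genes treated libraries of 1 age group as independent, so they may be too small.

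The share of counts in the 7 abundant genes differed by 5.86 on the log2 scale (58.3-fold) between both technical runs of 1 male sample, against a median of 1.10 between libraries of the same group (69 pairs, highest 4.09). A source in the handling of the library or of the RNA, after the sample was taken, is consistent with this, though it rests on 1 sample. Sex and age group gave an R2 of 0.462 for the log2 share against a median of 0.357 for shuffled groups (permutation p = 0.0961), so a part that follows the groups cannot be told apart from chance at this number of replicates. Outside the block the SD of log2 differences was 0.46 between the runs, against a median of 0.604 between libraries of a group, and 23 of the 69 pairs had a smaller SD than the runs (lowest 0.23). No biological cause of the block was tested, since its IDs carry no names.

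The median absolute slope of called genes was 0.267 per 10 days in males of 8 to 40 days and 0.151 in females of 10 to 80 days, but the order turned with females of 10 to 40 days (0.387, against 0.265 in males over the genes tested in both). These medians cover called genes only. With the 19 female libraries of 10 to 40 days fewer genes were called, and steeper slopes were needed to pass. The order of the medians therefore does not compare pace. The factor between male and female slopes over 15734 genes was 1.06 (95% interval 0.58 to 2.14, 400 resamples of the libraries), so whether 1 shared programme runs faster in males stays open, as the interval spans factors below and above 1. With females of 10 to 40 days the factor was 0.5 (95% interval -2.35 to 2.62). Shallow slopes were recovered less often in males on simulated counts (13 of 100 slopes of 0.25, against 69 in females), rates that do not carry over to the real data.

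Genes with consecutive ID numbers shared their direction by sex slightly more often than chance. Of 6429 such pairs with both genes called, 53.7% had the same direction, above the highest of 1000 shuffles (52%, permutation p = 0.000999, the smallest they can give). Pairs 2, 5 and 10 numbers apart gave 53.5%, 52.2% and 51.6%. Of 4848 pairs that lie 100 numbers apart 51.3% had the same direction (permutation p = 0.041, not adjusted), below the highest shuffle of 52.1%. Part of the excess may not be limited to close numbers, but this is not settled. Whether consecutive numbers mark neighbours on a chromosome is not given in the sources used here.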
